A study of Rattus norvegicus with 9 samples.

How the data were processed

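Total RNA from 9 cultures of primary rat Schwann cells was hybridised to Affymetrix rat expression arrays, 1 array per culture, in 3 groups of 3 independent replicates as the labels describe them. The deposited table holds 1 intensity per probe set and array on a linear scale, from 5.62 to 25800.2. The authors used RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes; the software, its version and the probe set definition are not given in the sources used here. Because the deposited intensities were linear, log2(value + 1) was taken, and fold changes are on that scale, which understates the change of dim probe sets. Arrays give no read depth, so their number limits the precision.

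The table holds 31099 probe sets. The 57 control probe sets of the manufacturer were left out of the tests, which leaves 31042. A platform annotation table paired 20826 of these with exactly 1 gene, 436 with several and 9780 with none listed, and no gene was named from the last 2 kinds. Symbols were brought up to date through the gene ID for 20764 probe sets, the accession for 2 and the older symbol for 53, using the RefSeq gene table of assembly GRCr8, and 13 kept the array's symbol. Each of the 14217 genes was represented by its probe set with the highest mean over the 9 arrays, and 4525 genes had more than 1. The other probe sets of a named gene did not all pass with it, as for Srf, Pdgfrb, Bdnf and Ccne2. No low-value filter was applied. Coordinates are not printed, since the build behind the probe sets is not given in the sources used here.

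Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a group means model over all 9 arrays with 6 residual degrees of freedom, Benjamini-Hochberg over genes, adjusted p under 0.05, no fold limit), and the same fit was run on all probe sets. The contrasts were NF1 RNAi against Control RNAi, NF1 RNAi + U0126 against NF1 RNAi, and NF1 RNAi + U0126 against Control RNAi. With no inhibitor-treated control cells analysed here, no interaction could be fitted. The sequences of the oligonucleotides are not given in the sources used here, so their effects on transcripts other than Nf1, such as Nras, were not tested. Gene lists (24 lists of 494 members, 438 measured) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over 72 tests (24 lists and 3 comparisons). No list call held with an estimated correlation. fry, which tests whether the genes of a list move one way on balance, passed 6, 7 and 14 lists in the 3 comparisons. Genes named in the text were Nf1 and Sema4f (the latter chosen from general knowledge of these cells, not from the labels), the 10 largest rises and 10 largest falls per comparison among genes past the threshold whose arrays did not overlap (leaving out provisional symbols), up to 4 passing members per list with the largest fold changes or, where none passed, the member with the smallest p, and the 5 changed-back genes per direction with the largest smaller fold change.

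The labels do not say what a shared replicate number marks. Deviations from the group means of same-numbered arrays correlated across genes in all 9 pairs, with r from 0.17 to 0.62. For different numbers r ran from −0.52 to 0.40. Of the 9 arrays, 5 correlated best with their own number in both other groups, since replicates 2 and 3 resembled each other. A pairing by number is therefore possible but not settled for replicates 2 and 3. The main fit leaves the number out, and the fit with it as a block, given as an alternative, has 4 residual degrees of freedom.

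Alternatives fixed before the data were examined were the replicate block, a filter at log2 6 in at least 3 arrays (10160 genes and 18638 probe sets left), median centring, quantile normalization, only the 2 groups compared, an intensity trend with robust eBayes, array weights, the mean of a gene's probe sets, a stricter adjusted p of 0.01, a 2-fold limit, each array left out in turn, and for lists the estimated correlation, fry and the block. Alternatives chosen after seeing the data were log2 without a pseudocount, leaving out all replicate 1 arrays, and for lists leaving out Control RNAi replicate 1, median centring and quantile normalization. The fit was tested on simulated arrays with 14217 genes, drawn with the fitted spread, for NF1 RNAi against Control RNAi. It recovered 71.6% of genes changed by 0.5, 97.0% of those changed by 1 and 95.5% of those changed by 2 on the log2 scale, and 4.5% of its calls were on unchanged genes. The simulation changed 220 genes, against 3735 called in the data, so these shares need not carry over. The root mean square error of its log2 fold changes was 1.12 times their mean standard error. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 in Python 3.11.15.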

Results

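Gene expression was measured in primary rat Schwann cells, the glia that ensheath and myelinate peripheral axons, prepared from sciatic nerve. The cells received scrambled control RNAi oligonucleotides or oligonucleotides against Nf1, which encodes neurofibromin, a GTPase-activating protein that switches Ras off. A further set of NF1 RNAi cells was also given U0126, an inhibitor of MEK, the kinase that activates ERK. RNA was taken 48 hours after transfection. The 3 groups (Control RNAi, NF1 RNAi, and NF1 RNAi + U0126) held 3 independent replicates each, 9 arrays in all. Control cells with U0126 were not analysed here, so the effect of the inhibitor was measured in NF1 knockdown cells. Fold changes below are log2 differences ± the standard error of the limma fit, group levels are mean log2 intensities ± SD, and n = 3 arrays per group throughout. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 14217 genes.

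The arrays were close in overall signal, with median intensities between 95.0 and 97.1 and between 58.0% and 58.5% of probe sets at a log2 value of 6 or more. The quantile normalization in RMA makes arrays alike in this way, so the closeness does not show that the samples were alike. The first principal component held 57.8% of the variance and placed the control arrays (−45.3 to −28.6) apart from the NF1 RNAi arrays (5.1 to 8.5) and the NF1 RNAi + U0126 arrays (25.2 to 30). The second held 20.1% and placed the NF1 RNAi arrays (−21.5 to −20.5) apart from both other groups (2.8 to 16.7). Control RNAi replicate 1 lay away from the other control arrays: the SD of its log2 differences was 0.31 to replicate 2 and 0.36 to replicate 3, against 0.15 between replicates 2 and 3. Replicate 1 was also the more distant array with NF1 RNAi (0.205 and 0.242, against 0.154) and with NF1 RNAi + U0126 (0.225 and 0.256, against 0.17). The third component, with 12.1% of the variance, placed the replicate 1 arrays of all 3 groups (13.2 to 18.5) apart from the rest (−16.9 to −2.4). Leaving out Control RNAi replicate 1 alone, as below, therefore removes only 1 group's part of a shared difference. The log2 difference between the 3′ and 5′ beta-actin control probe sets, a sign of RNA integrity, was 0.90 in Control RNAi replicate 1, 0.62 and 0.60 in the other control arrays, 0.78 to 0.85 with NF1 RNAi and 0.85 to 0.87 with NF1 RNAi + U0126. The same difference for GAPDH was 0.06, −0.06 and −0.11 in the control arrays, −0.10 to −0.02 with NF1 RNAi and −0.06 to −0.05 with NF1 RNAi + U0126.

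The targeted transcript was lower in every array that received NF1 oligonucleotides. Nf1 intensity was 88.3 ± 15.9 in control cells, 41.7 ± 0.667 with NF1 RNAi (47.2% of control) and 45.0 ± 5.8 with NF1 RNAi + U0126 (51.0% of control). On the log2 scale Nf1 fell by 1.05 ± 0.13 with NF1 RNAi (adjusted p = 0.000695), and its level with the inhibitor differed from that without it by 0.10 ± 0.13 (adjusted p = 0.694). The single Nf1 probe set lay near the low end of the array with NF1 RNAi (log2 5.39 to 5.44, the 32.5th to 33.0th percentile of all probe sets). Signal not due to Nf1 weighs more there, so 47.2% and 51.0% may overstate the share left. They are also ratios of means of 3 arrays, with control intensities from 70 to 99.3, and are not exact. Sema4f, a transmembrane semaphorin gene followed in every comparison, fell by 1.32 ± 0.27 with NF1 RNAi (adjusted p = 0.00732), from an intensity of 532 ± 195 to 205 ± 41.0. With U0126 its intensity was 373 ± 43.6, a log2 difference of 0.88 ± 0.27 from NF1 RNAi cells (adjusted p = 0.0665), which passed with the replicates as a block (adjusted p = 0.015). Against control cells the remaining difference was −0.44 ± 0.27 (adjusted p = 0.245), and without Control RNAi replicate 1 it was −0.78 (adjusted p = 0.00713).

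**Figure D1:**
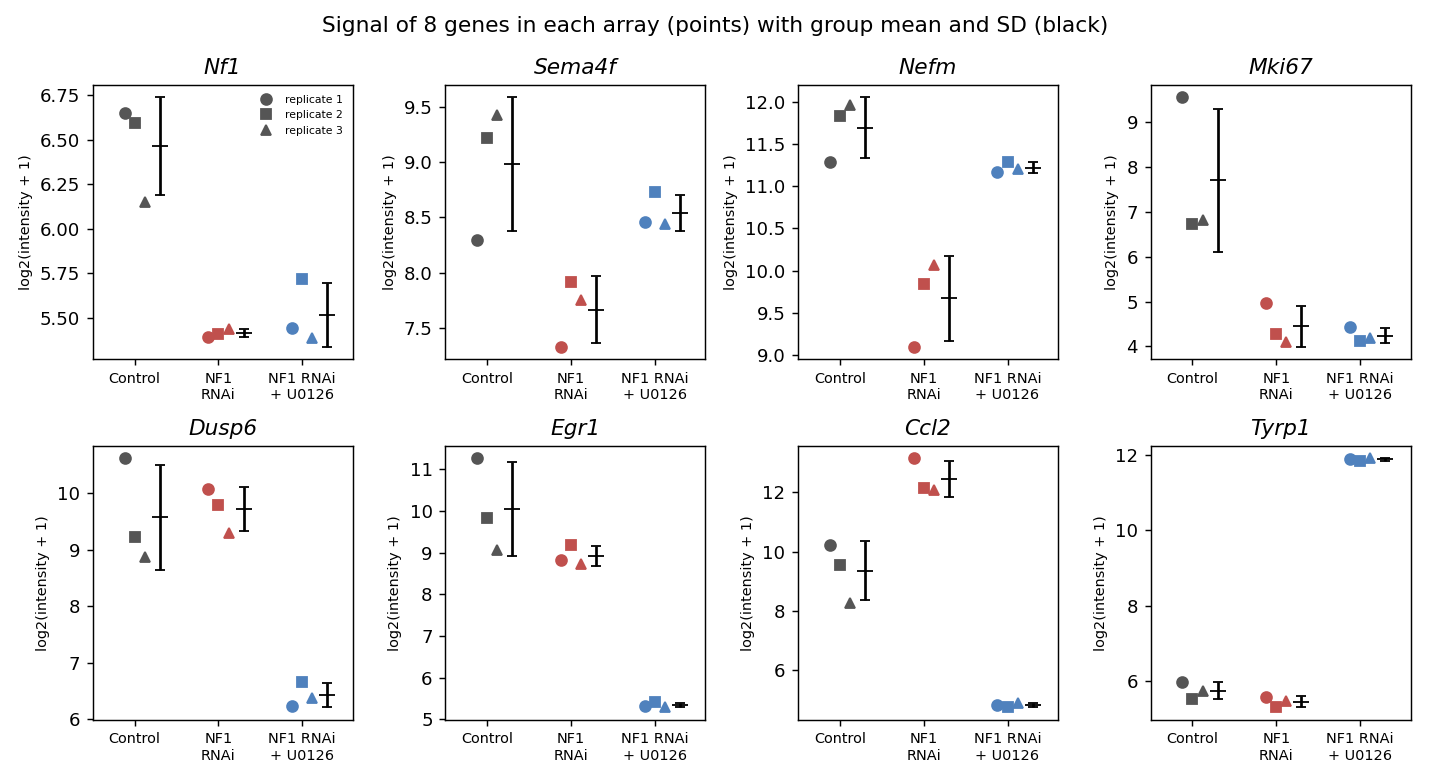
Log2 intensity (vertical axes) of 8 genes in each of the 9 arrays, by group (horizontal axes); symbols mark the replicate number, and black bars give the group mean and SD. Nf1 is lower in both groups with NF1 oligonucleotides, Ccl2 is higher with NF1 RNAi and lowest with U0126, and Tyrp1 is high in the U0126 arrays alone among the 3 groups.

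The first comparison asked what NF1 knockdown changed in the absence of the inhibitor. The largest rises were in Gal, which encodes the neuropeptide galanin and rose by 3.78 ± 0.19, Rasd1 (a Ras-like GTPase, 3.34 ± 0.30), Htr2b (a serotonin receptor, 3.26 ± 0.35), Aass (3.25 ± 0.41) and Ccl2 (a monocyte-attracting chemokine, 3.11 ± 0.45). Among the largest falls, Fst (follistatin, an activin antagonist) fell by 3.47 ± 0.36, Ccna2 (cyclin A) by 3.35 ± 0.60, Cavin3 by 3.30 ± 0.27 and Mki67 by 3.24 ± 0.65. In all, 3735 of 14217 genes passed an adjusted p of 0.05, 1850 higher and 1885 lower in NF1 RNAi cells, and 525 of them differed by at least 2-fold (147 higher, 378 lower). The 3 NF1 RNAi arrays did not overlap the 3 control arrays in 41.2% of genes, against 10% by chance. Over all probe sets, 6338 of 31042 passed, 3284 higher and 3054 lower.

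The other large rises were Dyrk3 (2.84 ± 0.20), the lysosomal and melanosomal glycoprotein gene Gpnmb (2.79 ± 0.28), Ccdc88c (2.60 ± 0.24), Dact2 (2.41 ± 0.26) and the integrin gene Itgax (2.29 ± 0.43). The other large falls were Ccn2 (connective tissue growth factor, −3.13 ± 0.49), Cdkn3 (−2.96 ± 0.57), Cdk1 (−2.87 ± 0.58), the cystine transporter gene Slc7a11 (−2.86 ± 0.59), Racgap1 (−2.78 ± 0.44) and Pimreg (−2.69 ± 0.72). Pimreg no longer passed when any 1 NF1 RNAi array was left out.

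Cell cycle genes fell together. Of 24 G2 and mitosis genes, 14 fell and none rose (19 fell when adjusted over the list alone), with a median log2 fold change of −1.72 and a camera adjusted p of 9e-07 (adjusted p = 0.83 with an estimated correlation). Besides Ccna2, Mki67 and Cdk1, Prc1 fell by 2.26 ± 0.53. Of 21 S phase and DNA replication genes, 10 fell and none rose (12 adjusted over the list alone; median −0.55, camera adjusted p = 5.6e-05, adjusted p = 0.83 with an estimated correlation). Members included Uhrf1 (−1.71 ± 0.41), Gins1 (−1.39 ± 0.29), Mcm3 (−0.78 ± 0.14) and Pola1 (−0.69 ± 0.14). The S phase median was 8.17 in Control RNAi replicate 1, 7.29 and 7.31 in the other control arrays and 7.33 to 7.42 with NF1 RNAi, and without that array the median fold change was −0.36, with 11 genes lower and a camera adjusted p of 0.00044. That array also carried the highest mitosis signal: the median of the 24 genes was 8.60, against 6.67 and 6.66 in the other control arrays and 5.68 to 6.20 with NF1 RNAi. Without it the median fold change was −0.98, and 17 of the 24 genes fell.

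Matrix, sterol and amino acid stress genes were lower as well. Of 24 extracellular matrix, integrin and laminin genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone, 14 and 1 with the replicates as a block; camera adjusted p = 0.0031, adjusted p = 0.71 with an estimated correlation). Lamb1 (a laminin chain) fell by 2.51 ± 0.20, Lama2 by 1.39 ± 0.17 and Col5a3 by 1.35 ± 0.41, while Itga7 rose by 1.47 ± 0.40. Of 23 cholesterol and fatty acid synthesis genes, 12 fell and none rose (13 adjusted over the list alone; camera adjusted p = 0.00049, adjusted p = 0.83 with an estimated correlation). The list was led by Dhcr7 (−1.70 ± 0.13), Insig1 (−1.39 ± 0.24), Elovl6 (−1.20 ± 0.30) and Cyp51 (−0.83 ± 0.18). Of 18 unfolded protein and amino acid stress genes, 8 fell and none rose (9 adjusted over the list alone, 12 fell and 2 rose with the replicates as a block; camera adjusted p = 0.0013, adjusted p = 0.83 with an estimated correlation). The largest falls were Slc7a11, Asns (asparagine synthetase, −2.26 ± 0.30), Chac1 (−1.22 ± 0.21) and Psat1 (−1.06 ± 0.26). Control RNAi replicate 1 was again the highest control array, at a median of 9.96 against 9.48 and 9.46 for the sterol genes and 10.04 against 9.22 and 9.33 for the stress genes. Without it 10 sterol genes fell and 2 rose (median −0.34, camera adjusted p = 0.0034), and 6 stress genes fell and 1 rose (median −0.33 instead of −0.52, camera adjusted p = 0.0099). Of 23 interferon response genes, 6 fell and none rose (6 adjusted over the list alone; camera adjusted p = 0.04, adjusted p = 0.83 with an estimated correlation, and 0.095 without Control RNAi replicate 1). Members included Ifi27 (−1.44 ± 0.08), Irf9 (−0.87 ± 0.13), Ifi44 (−0.45 ± 0.09) and Tap1 (−0.43 ± 0.12).

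ERK target genes did not move as a set with NF1 RNAi. Of all genes 26.3% passed in this comparison, 1850 higher and 1885 lower, and the share of the ERK list was near that. Of 20 ERK feedback and target genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.99): the phosphatase gene Dusp5 rose by 1.40 ± 0.24 and Ccnd1 (cyclin D1) by 0.75 ± 0.24, while Hbegf fell by 0.99 ± 0.29 and Epha2 by 0.67 ± 0.15. Without Control RNAi replicate 1, 5 rose and 1 fell, and the list median was 0.11 instead of −0.06 (camera adjusted p = 0.48). Of 16 immediate-early and AP-1 genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.38). Atf3 rose by 0.67 ± 0.17 and Myc (−0.73 ± 0.19), Klf6 (−0.73 ± 0.09) and Srf (−0.67 ± 0.08) fell. The other Srf probe sets differed by 0.03 and 0.16. Among 18 Ras-ERK pathway components 2 rose and 3 fell (2 and 4 adjusted over the list alone, 3 and 5 with the replicates as a block; camera adjusted p = 0.83). Nras fell by 1.65 ± 0.13 and Rasal2 by 0.77 ± 0.13, and Sos1 rose by 0.44 ± 0.06.

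Schwann cell genes were also mixed. Of 21 myelin and differentiation genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.82). Pmp22 fell by 1.96 ± 0.36, the myelination regulator Egr2 by 1.02 ± 0.14 and Prx by 0.62 ± 0.13, and S100b rose by 0.79 ± 0.07. Of 16 immature and repair Schwann cell genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.99): the adhesion molecules L1cam (−2.04 ± 0.14) and Ncam1 (−1.15 ± 0.25) fell, and Notch1 (0.73 ± 0.13) and Bdnf (0.67 ± 0.14) rose. The other Bdnf probe set differed by 0.11. Of 27 semaphorins and their receptors, 3 rose and 8 fell (3 and 8 adjusted over the list alone, 1 and 8 without Control RNAi replicate 1; camera adjusted p = 0.22): besides Sema4f, Nrp1 fell by 1.41 ± 0.42 and Sema6d by 0.90 ± 0.07, and Sema4d rose by 1.03 ± 0.22. Of 18 cell-cell and axon-glia adhesion genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.87). Ninj1 rose by 0.87 ± 0.09 and Chl1 by 0.77 ± 0.23. Of 15 Eph receptors and ephrins, 1 rose (Epha3, 1.02 ± 0.15) and 2 fell (Ephb4, −0.73 ± 0.10, and Epha2; the same counts adjusted over the list alone; camera adjusted p = 0.95).

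Among secreted and receptor genes, 6 of 22 cytokine and inflammatory genes rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.25). Ccl2 was followed by Ccl7 (1.72 ± 0.49), Spp1 (osteopontin, 1.14 ± 0.19) and Vegfa (0.74 ± 0.13). Of 24 growth factor receptors and ligands, 2 rose (Met, 2.27 ± 0.26, and Igf1, 2.01 ± 0.14) and 5 fell, including Pdgfrb (−1.37 ± 0.15; 2 and 5 adjusted over the list alone, 4 and 5 with the replicates as a block; camera adjusted p = 0.99). The other Pdgfrb probe sets differed by −0.28 and −0.08. Of 19 matrix proteases and inhibitors, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.82). Mmp17 (0.99 ± 0.14), Adamts4 (0.65 ± 0.09) and Mmp13 (0.49 ± 0.10) rose and Timp1 (−0.53 ± 0.05) fell. Mmp13 lay near the low end of the array in both control and NF1 RNAi cells (log2 3.98 and 4.48), so its expression is uncertain. None of 12 p53 target genes passed in limma over all genes or over the list alone (camera adjusted p = 0.46). At an unadjusted p under 0.05, 3 were higher, 4 passed as higher without Control RNAi replicate 1, 2 passed as higher and 1 as lower with the replicates as a block, and the smallest p was that of Plk2 (0.31 ± 0.10, adjusted p = 0.0515). Of 12 NRF2 targets 1 rose (Gclc, 0.44 ± 0.08) and 3 fell (Slc7a11; Gstm1, −0.94 ± 0.18; Srxn1, −0.39 ± 0.09; the same counts adjusted over the list alone; camera adjusted p = 0.55), and of 9 aryl hydrocarbon receptor targets 1 rose (Ahrr, 0.67 ± 0.21) and 2 fell (Cyp1a1, −1.28 ± 0.22, and Tiparp, −0.24 ± 0.08; the same adjusted over the list alone; camera adjusted p = 0.99).

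Markers of other cell types did not move as sets. Of 14 fibroblast markers, Col3a1 (−2.06 ± 0.36) and Mfap5 (−1.83 ± 0.22) fell and Ogn rose by 0.68 ± 0.17 (1 rose and 4 fell with the replicates as a block; camera adjusted p = 0.94). Of 16 macrophage and leukocyte markers, Laptm5 rose by 0.33 ± 0.06 (camera adjusted p = 0.25), and of 13 endothelial and mural markers, Acta2 fell by 0.52 ± 0.16 (camera adjusted p = 0.99). Adjusted over the list alone the counts were the same for fibroblast and macrophage markers, and Acta2 did not pass. Of 13 neuron markers, 1 rose (Rbfox3, 0.30 ± 0.08) and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.45), among them the neurofilament genes Nefl (−2.25 ± 0.35) and Nefm (−2.03 ± 0.25) and Uchl1 (−0.43 ± 0.13). Of the genes named as passing with NF1 RNAi, 21 lost the call when some single array was left out: Acta2, Ahrr, Atf3, Ccl7, Ccnd1, Chl1, Col5a3, Elovl6, Hbegf, Itga7, Myc, Nrp1, Ogn, Pimreg, Psat1, Rbfox3, Rgs4, Tap1, Tiparp, Uchl1 and Uhrf1.

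**Figure D2:**
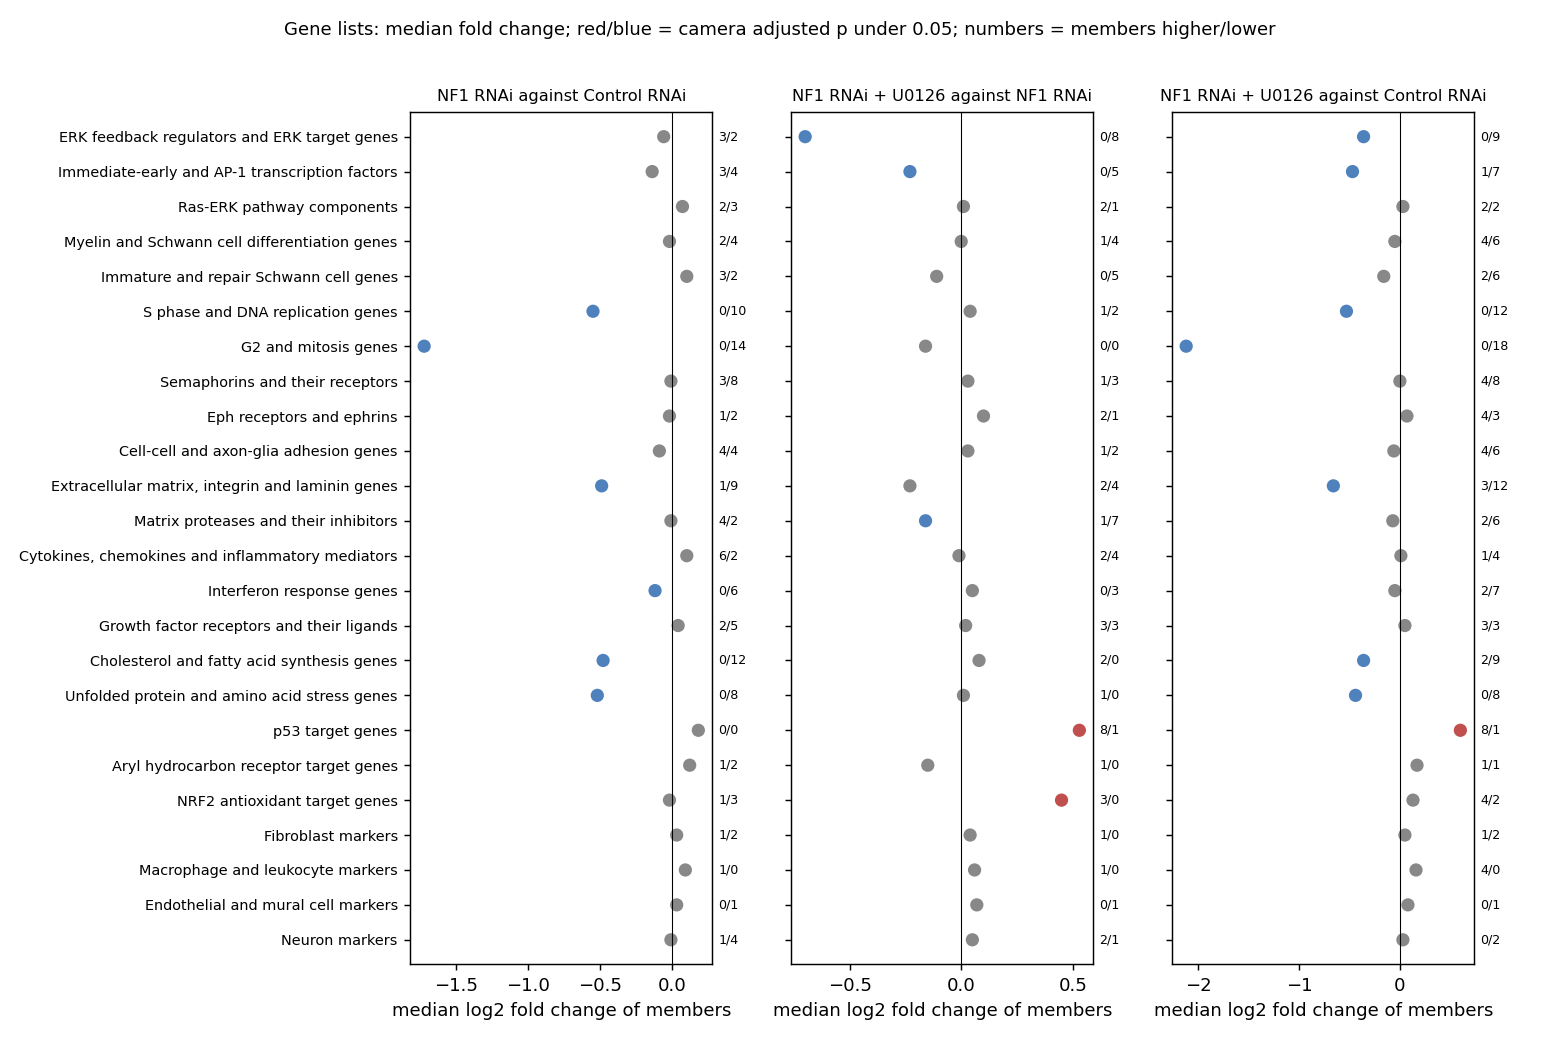
Median log2 fold change (horizontal axes) of the measured members of 24 gene lists in the 3 comparisons; red and blue points have a camera adjusted p under 0.05 with a preset correlation, and the figures at the right of each panel count members that rose and fell. The G2 and mitosis list lies at −1.72 with NF1 RNAi and at −0.16 for U0126 against NF1 RNAi.

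The second comparison asked what MEK inhibition changed in NF1 knockdown cells. Ccl2 fell by 7.65 ± 0.45, to a log2 level of 4.81 at the low end of the array, the transcription factor gene Egr1 by 3.56 ± 0.45 and the ERK phosphatase gene Dusp6 by 3.29 ± 0.40. The melanosomal enzyme gene Tyrp1 showed the largest rise, 6.41 ± 0.11, from a log2 level of 5.46 ± 0.14 near the low end of the array to 11.87 ± 0.03. Its other probe set rose by 4.58, from 4.89. It was followed by Synpr (4.04 ± 0.34), Lurap1l (3.63 ± 0.23), Zfp185 (2.86 ± 0.28) and Wscd1 (2.82 ± 0.09). In all 1951 genes passed, 953 higher and 998 lower with U0126, and 281 of them differed by at least 2-fold (122 higher, 159 lower). The 2 groups did not overlap in 33.9% of genes, against 10% by chance, and 3113 probe sets passed (1381 higher, 1732 lower). Without NF1 RNAi replicate 2 the count of genes was 1110, and without NF1 RNAi + U0126 replicate 2 it was 1226.

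Further large rises were Zfp503 (2.60 ± 0.31), Fyb1 (2.50 ± 0.17), Slc6a17 (2.48 ± 0.23), Rgs4 (2.34 ± 0.51) and Iqgap2 (2.31 ± 0.26). Further large falls were Sema3g (−3.71 ± 0.23), Celf4 (−3.39 ± 0.33), Ccl7 (−3.22 ± 0.49), the interferon-inducible GTPase gene Gbp2 (−3.22 ± 0.28), Rgs16 (−3.04 ± 0.41), Adamtsl1 (−3.0 ± 0.11) and Lgi4 (−2.81 ± 0.22), a Schwann cell secreted factor needed for myelination.

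Of 20 ERK feedback and target genes, 8 fell and none rose with U0126 (11 fell when adjusted over the list alone; median −0.70, camera adjusted p = 1.3e-05, adjusted p = 0.54 with an estimated correlation). Dusp6 was followed by Ccnd1 (−2.42 ± 0.24), Phlda1 (−1.85 ± 0.25) and Spry2 (−1.41 ± 0.13). Of 16 immediate-early and AP-1 genes, 5 fell and none rose (5 adjusted over the list alone; camera adjusted p = 0.0028, adjusted p = 0.53 with an estimated correlation). Egr1, Myc (−1.24 ± 0.19), Nr4a1 (−0.99 ± 0.10) and Fosl1 (−0.73 ± 0.15) were among them. Of 19 matrix proteases and inhibitors, 7 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0067, adjusted p = 0.53 with an estimated correlation). Members included Mmp17 (−1.85 ± 0.14), Timp3 (−1.58 ± 0.41), Adamts1 (−1.37 ± 0.22) and the urokinase receptor gene Plaur (−0.71 ± 0.11).

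The p53 and NRF2 target lists rose. Of 12 p53 targets, 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.53, camera adjusted p = 0.0021, adjusted p = 0.53 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, rose by 1.38 ± 0.12, Fas by 1.11 ± 0.26, Aen by 0.91 ± 0.18 and Zmat3 by 0.72 ± 0.17. Of 12 NRF2 targets, 3 rose and none fell (4 and 1 adjusted over the list alone, 5 and 1 with the replicates as a block, 6 and 0 without Control RNAi replicate 1; camera adjusted p = 0.0077, adjusted p = 0.53 with an estimated correlation). Taldo1 (0.79 ± 0.07), Txnrd1 (0.48 ± 0.07) and Gclc (0.46 ± 0.08). The cell cycle lists did not pass. None of 24 G2 and mitosis genes passed in limma, over all genes or over the list alone, and 0 did at an unadjusted p under 0.05 (Bub1, −0.87 ± 0.56, adjusted p = 0.371). The camera adjusted p was 0.48, and 0.0073 downwards without Control RNAi replicate 1, which enters through the shared spread. Of 21 S phase genes 1 rose (Cdt1, 0.52 ± 0.11) and 2 fell (Ccne2, −1.34 ± 0.28, and Mcm7, −0.30 ± 0.08; the same adjusted over the list alone; camera adjusted p = 0.82). The other Ccne2 probe set differed by 0.02.

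Among Schwann cell and guidance genes some fell and some rose, and none of these lists passed. Of all genes 13.7% passed in this comparison, so counts near that share do not set a list apart. Of 16 immature and repair Schwann cell genes, 5 fell and none rose (5 adjusted over the list alone; camera adjusted p = 0.064). Members included L1cam (−1.65 ± 0.14), the intermediate filament gene Gfap (−1.29 ± 0.32), Tnc (−1.16 ± 0.33) and Gdnf (−1.07 ± 0.16). Of 21 myelin and differentiation genes, 1 rose (Nab1, 0.43 ± 0.10) and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.29). Nab2 (−0.78 ± 0.15), Pmp2 (−0.63 ± 0.16) and Egr2 (−0.56 ± 0.14) were among the falls. Of 27 semaphorins and receptors, 1 rose (Plxna3, 0.85 ± 0.17) and 3 fell: Sema3g, Sema6d (−1.07 ± 0.07) and Plxnd1 (−0.73 ± 0.11; 5 rose and 5 fell adjusted over the list alone, 4 and 5 with the replicates as a block, 3 and 5 without Control RNAi replicate 1; camera adjusted p = 0.82). Of 15 Eph receptors and ephrins, Epha4 (1.19 ± 0.29) and Efna1 (0.61 ± 0.15) rose and Efnb1 fell by 0.95 ± 0.15 (3 and 2 adjusted over the list alone, 4 and 2 without Control RNAi replicate 1; camera adjusted p = 0.82). Of 18 adhesion genes, Nectin3 rose by 0.35 ± 0.06 and L1cam and Cadm1 (−0.97 ± 0.11) fell (1 and 2 adjusted over the list alone, 2 and 4 with the replicates as a block; camera adjusted p = 0.62). Of 24 matrix, integrin and laminin genes, 2 rose (Lamb2, 0.51 ± 0.07, and Dag1, 0.37 ± 0.08) and 4 fell, Lama4 by 0.97 ± 0.18 (2 and 6 adjusted over the list alone, 3 and 8 with the replicates as a block; camera adjusted p = 0.17).

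In the remaining lists, 2 of 22 cytokine genes rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.32). Il18 rose by 2.03 ± 0.16 and Spp1 fell by 1.17 ± 0.19. Of 23 interferon genes, 3 fell and none rose (3 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.94). Gbp2, Ifit2 (−1.50 ± 0.24) and Ifi27 (−0.40 ± 0.08). Of 24 growth factor receptors and ligands, 3 rose and 3 fell (4 and 5 adjusted over the list alone and with the replicates as a block, 3 and 5 without Control RNAi replicate 1; camera adjusted p = 0.99). Igf1 (1.55 ± 0.14) and Pdgfrb (1.07 ± 0.15) rose and Hbegf (−1.39 ± 0.29) and the neuregulin receptor gene Erbb3 (−1.08 ± 0.22) fell. Of 18 Ras-ERK components, Rasal2 (1.07 ± 0.13) and Map2k2 (0.43 ± 0.08) rose and Rasa2 fell by 0.51 ± 0.13 (2 and 2 adjusted over the list alone; camera adjusted p = 0.99). Of 23 sterol and fatty acid genes, Scd (1.33 ± 0.34) and Sqle (0.73 ± 0.16) rose (2 adjusted over the list alone; camera adjusted p = 0.25). Without Control RNAi replicate 1, 6 sterol genes rose (camera adjusted p = 0.054). Of 18 stress genes Herpud1 rose by 0.44 ± 0.09 (1 adjusted over the list alone, 3 rose and 2 fell with the replicates as a block or without Control RNAi replicate 1; camera adjusted p = 0.88), and of 9 aryl hydrocarbon receptor targets Tiparp rose by 1.26 ± 0.08 (1 adjusted over the list alone; camera adjusted p = 0.99). Single markers of other cell types passed, with the same counts adjusted over each list alone: the fibroblast marker Ogn (1.37 ± 0.17, camera adjusted p = 0.71), the macrophage marker Cd68 (0.90 ± 0.12, camera adjusted p = 0.62) and the neuron markers Nefm (1.55 ± 0.25) and Nefl (1.28 ± 0.35; list camera adjusted p = 0.60) rose, and the endothelial and mural marker Mcam (−1.89 ± 0.12, camera adjusted p = 0.99) and the neuron marker Uchl1 (−0.51 ± 0.13) fell. In this comparison 22 named calls were lost without some single array: Ccne2, Dag1, Efna1, Egr2, Epha4, Erbb3, Fas, Gfap, Hbegf, Herpud1, Mcm7, Nab1, Nefl, Pmp2, Rasa2, Rgs4, Scd, Sqle, Timp3, Tnc, Uchl1 and Zmat3.

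Genes changed by NF1 RNAi and changed back by U0126 were then counted. Ccl2, Htr2b (down to 4.98 ± 0.35, from 7.44 ± 0.58), Car8, Ccl7 and the muscle titin-cap gene Tcap led those that rose with NF1 RNAi and fell with the inhibitor. Synpr, Rgs4, Nefm, Phldb2 and Nefl led those that fell and then rose: Synpr went from 7.62 ± 0.18 in control cells to 5.20 ± 0.50 and then to 9.24 ± 0.69, and Nefm from 11.70 ± 0.36 to 9.67 ± 0.51 and then to 11.22 ± 0.06. In all 497 genes changed back, 302 higher then lower and 195 lower then higher, which is 13.3% of the genes changed by NF1 RNAi. With the replicates as a block the count was 808, without NF1 RNAi replicate 2 it was 284, without NF1 RNAi + U0126 replicate 2 it was 314, and without NF1 RNAi replicate 1 it was 323. Another 420 genes moved further in the same direction (212 higher, 208 lower), and 2818 (75.4%) did not pass for U0126 against NF1 RNAi.

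Both comparisons use the NF1 RNAi arrays, so part of the excess may come from those shared arrays. Independent lists would share 129.9 and 126.4 changed-back genes and 124 and 132.3 genes moved further, and 100 simulations of unchanged groups gave at most 1 changed-back gene, which does not gauge the excess among changed genes. The correlation of the fold changes across genes was −0.07, against −0.50 in the simulations, and their covariance was −0.0102, against −0.0079.

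**Figure D3:**
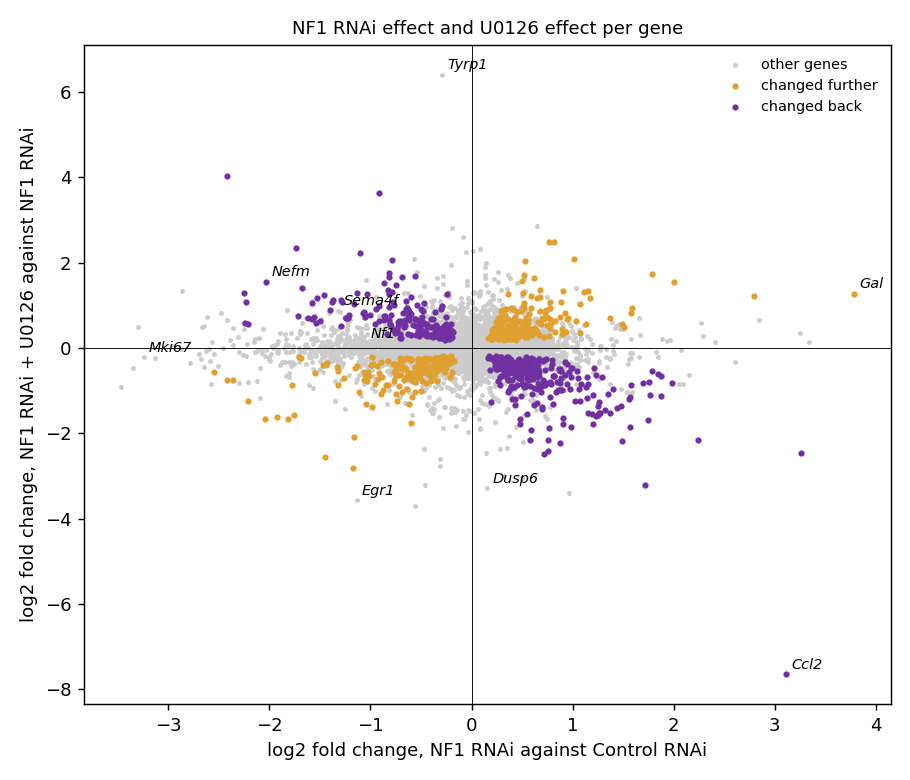
Log2 fold change of each gene with NF1 RNAi (horizontal axis) against its log2 fold change with U0126 in NF1 RNAi cells (vertical axis). Purple points are the 497 genes that passed in both comparisons with opposite signs, orange points the 420 that passed in both with the same sign, and grey points all others.

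The last comparison asked what still differed from control cells when MEK was inhibited. Tyrp1 (6.11 ± 0.11), Gal (5.05 ± 0.19), Gpnmb (4.01 ± 0.28), Aass (3.61 ± 0.41) and Igf1 (3.56 ± 0.14) rose most, and Egr1 (−4.70 ± 0.45), Ccl2 (−4.54 ± 0.45), Fst (−4.39 ± 0.36), Sema3g (−4.27 ± 0.23) and Ttyh1 (−4.00 ± 0.46) fell most. In all 5048 genes passed, 2545 higher and 2503 lower, and 874 of them differed by at least 2-fold (284 higher, 590 lower). The arrays did not overlap in 47.2% of genes, against 10% by chance, and 8710 probe sets passed (4395 higher, 4315 lower). Of the 3735 genes changed by NF1 RNAi, 2785 were changed in the same direction here (1299 higher, 1486 lower). Independent lists would share 331.2 and 331.9. The 100 simulations of unchanged groups gave at most 1, which does not gauge the excess among changed genes. Both sets of changes are against the same control arrays, so part of the excess may come from those arrays. Of the 497 changed-back genes, 332 did not pass against control, 77 kept the direction of the NF1 RNAi change and 88 passed in the opposite direction. Other large rises were Pkp4 (3.51 ± 0.15), Dyrk3 (3.51 ± 0.20), Zfp185 (3.50 ± 0.28), Rasd1 (3.48 ± 0.30) and Fyb1 (3.31 ± 0.17), and other large falls were Lgi4 (−3.98 ± 0.22), Ccna2 (−3.83 ± 0.60), L1cam (−3.69 ± 0.14), Gbp2 (−3.68 ± 0.28) and Egfl8 (−3.54 ± 0.32).

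Cell cycle genes stayed below control with the inhibitor. Of 24 G2 and mitosis genes, 18 fell and none rose (20 adjusted over the list alone; median −2.12, camera adjusted p = 9.7e-07, adjusted p = 0.83 with an estimated correlation). Members included Mki67 (−3.46 ± 0.65), Cdk1 (−2.89 ± 0.58) and Bub1 (−2.48 ± 0.56). Without Control RNAi replicate 1, whose mitosis signal was the highest, the median was −1.22 and 20 fell. Of 21 S phase genes, 12 fell and none rose (13 adjusted over the list alone; camera adjusted p = 0.00049, adjusted p = 0.83 with an estimated correlation). Members included Ccne2 (−1.77 ± 0.28), Uhrf1 (−1.72 ± 0.41), Gins1 (−1.28 ± 0.29) and Pola1 (−0.88 ± 0.14). Without Control RNAi replicate 1 the S phase median was −0.35 instead of −0.53.

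Of 20 ERK feedback and target genes, 9 fell and none rose (9 adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.71 with an estimated correlation). Dusp6 (−3.14 ± 0.40), Hbegf (−2.37 ± 0.29), Etv5 (−1.91 ± 0.44) and Spry2 (−1.81 ± 0.13). Of 16 immediate-early genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.0059, adjusted p = 0.53 with an estimated correlation), with Myc (−1.97 ± 0.19), Klf6 (−1.13 ± 0.09) and Fosl1 (−0.94 ± 0.15) beside Egr1. Of 24 matrix, integrin and laminin genes, 12 fell and 3 rose (12 and 3 adjusted over the list alone; camera adjusted p = 0.0026, adjusted p = 0.71 with an estimated correlation). Members included Lamb1 (−2.92 ± 0.20), Col5a3 (−2.60 ± 0.41), Lama4 (−1.61 ± 0.18) and Tnc (−1.58 ± 0.33). Of 12 p53 targets, 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0056, adjusted p = 0.54 with an estimated correlation). The list was led by Mdm2 (1.72 ± 0.12), Cdkn1a (1.42 ± 0.48), Aen (1.16 ± 0.18) and Zmat3 (1.15 ± 0.17).

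Of 18 unfolded protein and amino acid stress genes, 8 fell and none rose (8 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.83 with an estimated correlation, and 0.079 without Control RNAi replicate 1). Members included Asns (−1.68 ± 0.30), Phgdh (−0.90 ± 0.23), Pdia4 (−0.87 ± 0.22) and the chaperone gene Hspa5 (−0.84 ± 0.15). Of 23 sterol and fatty acid genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.04, adjusted p = 0.92 with an estimated correlation). That call was lost with the replicates as a block (adjusted p = 0.075) and without Control RNAi replicate 1 (adjusted p = 0.32). Dhcr7 (−1.37 ± 0.13), Insig1 (−1.36 ± 0.24) and Cyp51 (−0.81 ± 0.18) fell and Scd rose by 1.86 ± 0.34. Without Control RNAi replicate 1, 7 sterol genes fell and 4 rose.

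The lists that did not pass against control held large single changes. Of all genes 35.5% passed in this comparison, so counts near that share do not set a list apart. Among 27 semaphorins and receptors 4 rose and 8 fell (the same adjusted over the list alone, 2 and 8 without Control RNAi replicate 1; camera adjusted p = 0.25), with Sema6d at −1.97 ± 0.07, Plxnd1 at −0.92 ± 0.11 and Nrp2 at 0.71 ± 0.13. Among 21 myelin and differentiation genes 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.46). Pmp22 (−1.96 ± 0.36), Egr2 (−1.58 ± 0.14), Pmp2 (−1.17 ± 0.16) and Nab2 (−0.77 ± 0.15) fell. Among 16 immature and repair genes 2 rose and 6 fell (5 and 7 adjusted over the list alone, 5 and 6 with the replicates as a block, 4 and 7 without Control RNAi replicate 1; camera adjusted p = 0.45). Gfap (−1.95 ± 0.32) and Cdh2 (−1.31 ± 0.33) fell. Among 18 adhesion genes 4 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.71). Ninj1 (0.93 ± 0.09) and Chl1 (0.91 ± 0.23) rose. Among 15 Eph receptors and ephrins 4 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.99). Epha4 (1.94 ± 0.29) and Efna1 (0.63 ± 0.15) rose and Efnb1 (−0.97 ± 0.15) and Ephb4 (−0.63 ± 0.10) fell. Among 19 matrix proteases and inhibitors 2 rose and 6 fell (the same adjusted over the list alone, 4 and 7 without Control RNAi replicate 1; camera adjusted p = 0.25). Timp3 (−2.17 ± 0.41), Adamts1 (−1.20 ± 0.22), Mmp17 (−0.87 ± 0.14) and Timp1 (−0.86 ± 0.05) fell. Among 22 cytokine genes 1 rose (Il18, 2.56 ± 0.16) and 4 fell, including Ccl7 (−1.50 ± 0.49) and Cxcl1 (−0.52 ± 0.12; 1 and 3 adjusted over the list alone, 3 and 3 without Control RNAi replicate 1; camera adjusted p = 0.99). Among 23 interferon genes 2 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.088, and 0.038 with quantile normalization). Ifi27 (−1.84 ± 0.08) and Ifit2 (−1.70 ± 0.24) fell and Isg20 (0.89 ± 0.15) rose. Cxcl1, named above, lay near the low end of the array in both control and NF1 RNAi + U0126 cells (log2 4.76 and 4.25), so its expression is uncertain.

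Among 24 growth factor receptors and ligands 3 rose and 3 fell (the same adjusted over the list alone, 3 and 5 with the replicates as a block, 3 and 6 without Control RNAi replicate 1; camera adjusted p = 0.94). Met rose by 2.85 ± 0.26 and Igf1r fell by 0.76 ± 0.07. Among 18 Ras-ERK components 2 rose (Sos1, 0.57 ± 0.06, and Mras, 0.35 ± 0.10) and 2 fell (Nras, −1.74 ± 0.13, and Nf1, −0.95 ± 0.13; the same adjusted over the list alone, 4 and 5 with the replicates as a block; camera adjusted p = 0.84). Among 12 NRF2 targets 4 rose and 2 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.82). Taldo1 (0.94 ± 0.07), Gclc (0.90 ± 0.08) and Hmox1 (0.56 ± 0.16) rose and Gstm1 (−0.69 ± 0.18) fell, and among 9 aryl hydrocarbon receptor targets Tiparp rose by 1.01 ± 0.08 and Cyp1a1 fell by 1.67 ± 0.22 (the same adjusted over the list alone; camera adjusted p = 0.82). Of the markers of other cell types, Ogn rose by 2.05 ± 0.17 while Mfap5 (−1.92 ± 0.22) and Col3a1 (−1.60 ± 0.36) fell (fibroblast list, 2 rose and 4 fell with the replicates as a block, camera adjusted p = 0.99). In the macrophage list 4 of 16 rose, Cd68 by 1.07 ± 0.12 and Tyrobp, Fcer1g and Laptm5 by 0.29 ± 0.09, 0.28 ± 0.08 and 0.20 ± 0.06 (camera adjusted p = 0.12). Mcam fell by 1.80 ± 0.12 (endothelial and mural list, camera adjusted p = 0.99), and of 13 neuron markers Uchl1 (−0.94 ± 0.13) and Scn9a (−0.21 ± 0.05) fell (4 fell with the replicates as a block; camera adjusted p = 0.83). The counts of these marker lists were the same adjusted over each list alone. Tyrobp (log2 4.30 and 4.59), Fcer1g (4.83 and 5.11) and Scn9a (3.38 and 3.17) lay near the low end of the array in both control and NF1 RNAi + U0126 cells. Their expression is therefore uncertain. Leaving out some single array lost 9 named calls against control: Ccl7, Cdh2, Cdkn1a, Fcer1g, Hmox1, Laptm5, Mras, Scn9a and Tyrobp.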

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

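Of the tests in this part, those of the mitosis genes and of the ERK list genes were chosen after the results they bear on had been seen; those of Tyrp1 (with a list drawn up after its rise was seen) and of the other splits were written before their values. The RNA quality test replaced an earlier form that rested on 1 array and argued against that explanation, and the fibroblast test was widened from 2 to 4 transcripts. The control probe sets of the manufacturer lie outside the comparisons of the report. Among them, 3 hexokinase probe sets were higher with NF1 RNAi than in control cells, with no overlap between the arrays: the 3′ set by 0.74 (limma adjusted p = 0.00145 over the control probe sets), the 5′ set by 0.82 (adjusted p = 0.0113) and the middle set by 0.56 (adjusted p = 0.00145). With U0126 against NF1 RNAi the 3′ set (−0.57, adjusted p = 0.0255) and the middle set (−0.38, adjusted p = 0.0285) fell, the 5′ set did not pass (−0.70, adjusted p = 0.0585), and none passed against control. Of the beta-actin control sets, the 3′ set (−0.34, adjusted p = 0.00524) and the 5′ set (−0.46, adjusted p = 0.00928) fell with NF1 RNAi and the middle set did not pass (adjusted p = 0.0655).

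For each comparison the 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05; in each, 1 split, the real one, gave as many genes. The real split gave 3735, 1951 and 5048 genes in the order of the report, and the highest of the other splits gave 0 by limma in each (at an unadjusted p under 0.05, 5208, 3870 and 6341 genes against at most 718, 972 and 820). Among the 4 splits that part all same-numbered pairs, the highest of the others was also 0. Every other split mixes arrays of both groups, so the group difference itself widens the spread within it and lowers its count. The counts of the other splits therefore do not show how many genes chance would give, and no conclusion is drawn from them.

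Mitosis genes were lower with NF1 RNAi. Control RNAi replicate 1 alone does not account for it, since the median fold change without that array was −0.98 with 17 of 24 genes lower. The test for dividing fibroblasts lost from the NF1 RNAi cultures used Dcn, Lum, Pdgfra and Dpt. They reached at most 5.33 in any control array, which argues against that explanation for these transcripts only. Col3a1, however, had a mean of 12.33 in control cells and 10.27 with NF1 RNAi. Mfap5 also fell, from 7.21 to 5.38, while Ogn rose. A loss of fibroblasts therefore stays open. RNA quality stays open, because the 3′ to 5′ beta-actin difference was 0.11 higher on average with NF1 RNAi than in control cells but highest in Control RNAi replicate 1, while the GAPDH difference was about equal (0.06, −0.06 and −0.11 in control arrays, −0.02, −0.06 and −0.10 with NF1 RNAi).

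Tyrp1 rose with U0126 in both of its probe sets, by 6.41 and 4.58, from levels near the low end of the array (5.46 and 4.89). The test for pigment cells in the U0126 cultures used Tyr, Dct, Pmel and Mlana, of which the largest rise was 0.07. Tyr, Dct and Mlana lay near the low end of the array in every group (4.91 to 5.20), with 1 probe set each. Whether those probe sets can detect their transcripts was not shown. Pmel, at 8.34 with NF1 RNAi, differed by −0.33 with U0126, which argues against pigment cells for that transcript only. A joint rise of pigment cell genes was not found either: without Tyrp1 the list of 11 measured genes gave a camera adjusted p of 0.54 over 15 tests, though Gpnmb (1.22) and Kit (1.53) rose. A response of Tyrp1 itself to U0126 in these NF1 RNAi Schwann cells may be worth following up, as a hypothesis. Whether it runs through MEK was not tested. The transcript of Mitf, the known activator of Tyrp1, differed by 0.13 in the probe set used, 1 of 2 (limma adjusted p = 0.567). The level and activity of its protein were not analysed here, so a part of Mitf in the rise stays open.

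Of the 8 ERK list genes that fell with U0126, 3 rose with NF1 RNAi, 1 fell and 4 did not pass, with a median of 0.30. These 8 were chosen for a fall from the same NF1 RNAi arrays, which by itself raises their NF1 RNAi values. Over the whole list of 20 the median was −0.06, 3 rose and 2 fell with NF1 RNAi, and 5 rose and 1 fell without Control RNAi replicate 1. With all arrays the share that passed was near the 26.3% of all genes, so the counts do not set the list apart from other genes. That does not show that none of its members responded. A ceiling of the array is argued against by the levels of the 8 genes. The highest control mean among them was 11.65, while the brightest probe set reached an intensity of 25800.2. Whether the Nf1 left after knockdown limited their rise cannot be told apart from other reasons, because the lowest of its NF1 RNAi signals, at the 32.5th percentile of probe sets, lay near the low end of the array, which shows neither that Nf1 was left nor how much, and no protein or ERK activity was analysed here. With no inhibitor-treated control cells, the U0126 effect in cells with normal Nf1 was not tested.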

How the results depend on the processing

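Nf1 fell under every alternative, by 0.96 to 1.21 when single arrays were left out. With array weights (the fit stopped before full convergence) the counts of genes were 5982 for NF1 RNAi and 3261 for U0126 against NF1 RNAi, and 1009 genes changed back; the cause was not tested. An adjusted p of 0.01 gave 2118, 904 and 3304 genes in the 3 comparisons and a 2-fold limit 525, 281 and 874, as stricter limits must. The replicate block raised the changed-back count from 497 to 808 and turned the calls of Sema4f for U0126 and of the sterol list against control; it changed no other call of a named gene or of the 24 lists, and took the added YAP and TEAD list against control from an adjusted p of 0.057 to 0.049. Counts of passing list members moved by over 1.5 times in 37 of 144 cases with the block, such as matrix genes lower with NF1 RNAi (9 to 14), and in 38 without Control RNAi replicate 1. Leaving out single arrays gave 2791 to 3607 genes for NF1 RNAi, 1110 to 1612 for U0126, 4109 to 5090 against control, 284 to 620 changed back, and 4550 to 6173, 1676 to 2449 and 6978 to 8923 probe sets. Fewer arrays mostly gave fewer calls, but leaving out Control RNAi replicate 1 gave the 5090, 620 and 8923; the cause was not tested, and no gene called in both fits changed direction. Without the 3 replicate 1 arrays, chosen after seeing the data, Nf1 fell by 0.95, the counts of genes were 3828, 2616 and 5427, and 701 changed back. Of 274 named gene results past the threshold, 218 passed under every other fit tried and 56 were lost under at least 1 (52 without some single array), and none reversed; 4 of the 5 not past it passed under at least 1; the stricter limits on p and fold were not applied to them. Of 19 list calls, all 19 were lost with an estimated correlation, 4 with fry (mitosis and sterol genes with NF1 RNAi, sterol and stress genes against control), 3 without Control RNAi replicate 1 (interferon genes with NF1 RNAi, sterol and stress genes against control), 1 with the block and 1 with quantile normalization (both sterol genes against control). Calls were also gained: mitosis genes for U0126 against NF1 RNAi without Control RNAi replicate 1 (0.0073), interferon genes against control with quantile normalization (0.038), and others with fry.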

Other observations

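The lists in this part were drawn up after the results of the report had been seen: the fall of Ccn2 prompted the first, those of Acta2 and of beta-actin control probe sets the second, and the rise of Gpnmb the third. The tests of the full lists were written before their results, and those without the prompting genes after. Camera adjusted p-values are over 15 tests, and over 21 where a prompting gene was left out.

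Actin cytoskeleton genes fell with NF1 RNAi. Of 17 measured targets of SRF, the transcription factor that follows actin assembly, 10 fell and none rose (median −0.44, camera adjusted p = 8e-05, adjusted p = 0.23 with an estimated correlation). The falls included Tagln (−2.63), the calponin gene Cnn2 (−1.25), Fhl2 (−1.21), Zyx (−1.16), Actg1 (−1.14), Flna (−1.09) and Srf itself (−0.67). Without Acta2 the camera adjusted p was 1e-04, with 9 of 16 genes lower (beta-actin was tested only through the control probe sets, outside the list). Srf stayed among the 16 although its fall had been seen before, so the reduced list is not independent of these results. The other Srf probe sets differed by 0.03 and 0.16. With U0126 against NF1 RNAi, 1 rose and 2 fell, and against control 9 fell.

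Targets of YAP and TEAD, which respond to cell tension and density, moved both ways with NF1 RNAi. Of 17 measured, 8 fell and 3 rose (median −0.39, camera adjusted p = 0.032, adjusted p = 0.23 with an estimated correlation). Without Control RNAi replicate 1 the median was −0.18 and the adjusted p 0.07. The falls included Ccn1 (−2.14), Ajuba (−1.40), Ankrd1 (−1.33) and Axl (−0.80). Without Ccn2 the median was −0.32, with 7 of 16 genes lower and 3 higher. The camera adjusted p was then 0.062 over 21 tests (unadjusted p = 0.027), so a joint fall of this list stays undecided.

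Of 21 measured lysosome genes, 6 rose and none fell with U0126 against NF1 RNAi (median 0.23, camera adjusted p = 3e-04, adjusted p = 0.23 with an estimated correlation). Npc2 rose by 0.54, Tpp1 by 0.44 and Ctsb by 0.34. With NF1 RNAi alone 5 rose and 2 fell (camera adjusted p = 0.083), and with both against control 12 rose. Neu1 (0.85), Lamp2 (0.68) and Ctsa (0.66) were among these 12, but they had risen with NF1 RNAi alone (0.74, 0.41 and 0.35) and did not pass for U0126 against NF1 RNAi. A joint rise of lysosome genes with U0126 may be a hypothesis worth testing (camera adjusted p = 3e-04, or 0.23 with an estimated correlation).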
